A study of Homo sapiens with 6 samples.

How the data were processed

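Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map γH2AX, the phosphorylated form of the histone variant H2AX that forms on chromatin around DNA double strand breaks. The cells were DLD1, an established human colorectal cancer line, either wild type for UNG (WT) or with UNG knocked out (KO). UNG is the uracil DNA glycosylase that removes uracil from DNA at the start of base excision repair. Each genotype was left untreated, treated with pemetrexed (an antifolate that blocks thymidylate synthesis) or treated with cisplatin (a platinum compound that crosslinks DNA). There were 6 libraries, 1 for each of the 6 groups. Groups were taken from the sample titles. The doses and treatment times are not given in the sources used here.

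Per the submitters' processing notes, the tools named were Bowtie, with no version, and MACS 1.4, and the genome build was hg18. The control library, the calling threshold and any filter are not given in the sources used here. The deposited files analysed here are 4 peak lists, 1 for each drug-treated library. Per the file headers, each row holds a chromosome, a start and an end, and nothing else. The files give no height, fold, score, p-value, false discovery rate or read count for a peak. The untreated libraries were not analysed here, and they have no peak list to set beside the 4 lists. Whether the peaks of a treated library were called against an untreated one is not known. The read depth of each library is unknown. A deeper library, or a different control, can change the number, width and place of called peaks, and no value here corrects for that. No list held a duplicated row or peaks that overlapped each other (0 of each). Positions are printed as the files list them, in hg18. Whether starts count from 0 or from 1 is not given in the sources used here, so each start may differ by 1 bp from its place in a genome browser.

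The only gene table at hand was for another genome build. It was not used, because positions were not converted between builds. For this reason no peak is assigned to a gene, exon or intron, and the 7 gene lists drawn up for the study were not tested. Chromosomes are described as gene-dense (16, 17, 19 and 22) or gene-poor (4, 13 and 18) from general knowledge, a grouping made after the counts per chromosome had been seen.

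The gene lists, the ratios of peak numbers and covered bases, the overlap, chromosome and cluster tests and most alternatives were fixed before the data were examined. The intervals of the covered bases, the thinned lists, the groups of chromosomes, the share of peaks within 5 Mb of the first or last covered position (the last alone on chromosomes 13, 14, 15, 21 and 22), the window counts beyond the named windows and their correlations were added afterwards. Numbers of peaks were compared as ratios with exact (Clopper-Pearson) 95% intervals. Covered bases were compared as ratios with percentile intervals from 2000 resamplings of the peaks. The KO over WT ratios of the 2 drugs were compared by a conditional odds ratio with its exact interval. All intervals cover counting error between lists only, since each group has 1 library. They treat peaks as independent, so where neighbouring peaks belong together the intervals are too narrow. Lists were intersected pairwise at a minimum of 1 bp. The number of peaks of the shorter list that met the longer list was compared with 10000 circular shifts of the shorter list within each chromosome, between the first and last position covered by any list. One-sided permutation p-values were adjusted by Benjamini-Hochberg over the 6 pairs, and 1e-04 is the smallest unadjusted p that these shifts can give. The share of a list's peaks on each chromosome was compared between genotypes by Fisher's exact test, two-sided, adjusted over 24 chromosomes at a threshold of 0.05. This test compares 2 lists and treats peaks as independent, which neighbouring peaks are not. The share of peaks within 100 kb of another peak was compared with 10000 random placements of the same peaks on their own chromosomes, a reference that ignores unsequenced stretches. Peaks on unplaced contigs were left out of the overlap, cluster and window analyses.

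The rule for named regions asked for the 5 peaks per list with the highest fold. Because the files give no fold or score, the 5 widest peaks per list were used instead. The rule further named regions with a peak in all 4 lists, the 5 windows of 1 Mb with the most KO pemetrexed peaks and no WT pemetrexed peak, and the 5 windows with the most peaks over all lists. Stricter thresholds, a MACS score of at least 100 and a false discovery rate of at most 5%, could not be applied for the same reason. Ratios and clusters were recomputed with peaks within 10 kb joined, the chromosome test with peaks within 100 kb joined, and clusters at a distance of 1 Mb. Overlaps were recomputed with a reciprocal overlap of 50%, a tolerance of 10 kb, and random placement in place of shifts. Ratios, overlaps and clusters were recomputed without chromosome 19, which held the most peaks. Chosen after the data were seen were ratios with peaks within 100 kb joined, peaks of at least 600 bp alone, ratios and overlaps without chromosomes 16, 17, 19 and 22, and overlaps against local shifts of 100 kb to 1 Mb. Joined ratios were set beside those of 1000 random placements of each list on its own chromosomes, joined in the same way.

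The interval tests were checked on 100 simulated lists of 916 peaks, the number of placed WT pemetrexed peaks. The simulated lists kept the real widths and numbers per chromosome but were placed at random, and 200 placements were used in each test. For unrelated lists the overlap test gave p under 0.05 in 1% of simulations. This does not show the rate of false calls for lists whose peaks cluster, as the real ones do. With 45 peaks planted on a randomly placed list of the size of the KO pemetrexed list, it did so in 100% and recovered a mean excess of 44.1 peaks. The cluster test gave p under 0.05 in 5% of random lists and in 100% of lists with planted neighbours. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.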

Results

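γH2AX peaks were compared between UNG wild-type (WT) and UNG knockout (KO) DLD1 colorectal cancer cells after pemetrexed or cisplatin. The 4 drug-treated libraries gave 4 peak lists, 1 per group. The WT pemetrexed list held 924 peaks, the WT cisplatin list 1807, the KO pemetrexed list 5278 and the KO cisplatin list 4570. With 1 library per group and unknown read depth, differences between lists have no replicate check, and the intervals given cover counting error only.

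The first question, posed by the design, was how loss of UNG changed the γH2AX peaks found after pemetrexed. The KO pemetrexed list held 5.71 times as many peaks as the WT pemetrexed list (95% interval 5.33 to 6.13). It covered 8.97 Mb of the genome against 0.559 Mb, a ratio of 16.03 (95% interval 14.9 to 17.3). The larger ratio of bases reflects wider peaks. The median width was 1172 bp (interquartile range 907 to 1888) in the KO pemetrexed list and 585 bp (548 to 639) in the WT pemetrexed list. Peaks of 2 kb or more made up 22.6% of the KO pemetrexed list (95% exact binomial interval 21.5 to 23.8%) and 0 of 924 WT pemetrexed peaks, for which 3 counts would be a share of 0.325% and the exact upper bound is 0.398%. The excess in number depended on how neighbouring peaks were counted. With peaks within 10 kb joined, the ratio was 3.76, and with peaks within 100 kb joined it was 1.41 (1204 against 854 regions), where peaks placed at random on their chromosomes and joined gave 3.94. It was 3.79 without chromosomes 16, 17, 19 and 22, and 15.6 with peaks of at least 600 bp alone, a filter that restates the difference in width by leaving 335 WT and 5212 KO peaks.

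The 5 widest KO pemetrexed peaks lay on 5 different chromosomes. The widest spanned 21459 bp on chromosome 10 (134114109 to 134135568), and the WT cisplatin list also had a peak there. The next were 17262 bp on chromosome 22 (44895197 to 44912459), 17255 bp on chromosome 20 (60228978 to 60246233), 16585 bp on chromosome 19 (18738924 to 18755509) and 15871 bp on chromosome 17 (76714584 to 76730455). The last also met a KO cisplatin peak. None of these 5 regions held a WT pemetrexed peak. The widest WT pemetrexed peak was 1851 bp on chromosome 10 (39121794 to 39123645), and the other four were 1196 to 1518 bp, on chromosomes 2, 10 and 16. No other list had a peak at any of those 5 places.

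**Figure D1:**
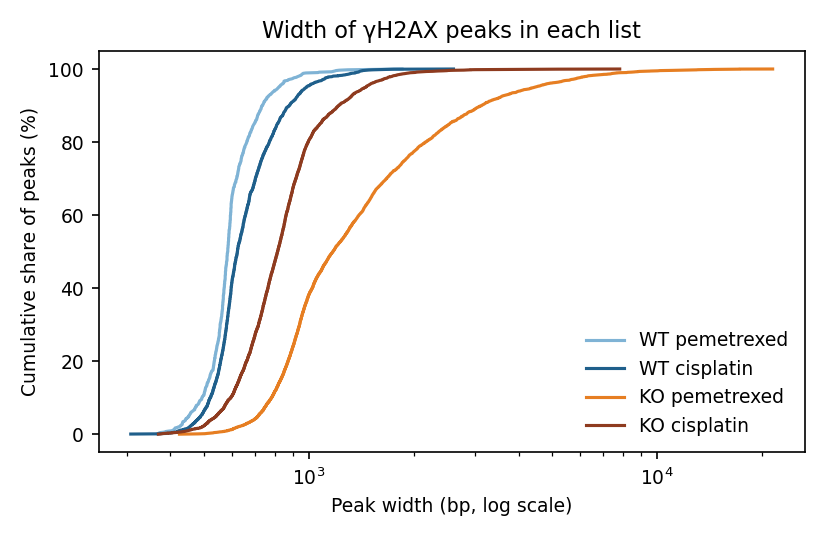
Cumulative share of peaks (y axis, %) against peak width (x axis, bp, log scale), with 1 line for each of the 4 lists. The KO pemetrexed line lies to the right, with a median of 1172 bp against 585 bp for WT pemetrexed, 623 bp for WT cisplatin and 813 bp for KO cisplatin.

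After cisplatin the KO list was also the longer one, by a smaller factor. It held 2.53 times as many peaks as the WT cisplatin list (95% interval 2.39 to 2.67) and covered 3.99 Mb against 1.21 Mb, a ratio of 3.29 (95% interval 3.11 to 3.48). Median widths were 813 bp (interquartile range 690 to 953) in KO and 623 bp (571 to 731) in WT. Peaks of 2 kb or more made up 0.985% of the KO cisplatin list and 0.0553% (1 peak) of the WT cisplatin list. The widest KO cisplatin peak was 7807 bp on chromosome 2 (132745257 to 132753064). Others of the 5 widest were on chromosome Y (6170 and 4699 bp), chromosome 8 (5167 bp) and chromosome 16 (4407 bp). In the WT cisplatin list the widest peak was 2601 bp on chromosome 19 (18473692 to 18476293), which the KO pemetrexed list also covered, and the next was 1748 bp on chromosome 17.

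The KO over WT ratio of peak numbers was higher for pemetrexed than for cisplatin by a factor of 2.26 (95% exact interval 2.07 to 2.47). This direction turned when peaks within 100 kb were joined, where the factor was 0.754 (95% interval 0.676 to 0.841) against 1.78 with randomly placed peaks joined. Within WT cells, the pemetrexed list was 0.511 times as long as the cisplatin list (95% interval 0.472 to 0.554). Within KO cells it was 1.15 times as long (95% interval 1.11 to 1.202). The KO ratio fell below 1 when peaks within 10 kb were joined (0.815), when peaks within 100 kb were joined (0.43, with 0.945 from randomly placed peaks) and without chromosomes 16, 17, 19 and 22 (0.866).

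The KO pemetrexed peaks were distributed over the chromosomes differently from the other lists. Chromosome 19, the most gene-dense human chromosome, held 14.2% of the KO pemetrexed peaks (751) and 3.25% of the WT pemetrexed peaks (30), with an odds ratio of 4.94 (95% interval 3.41 to 7.43). Chromosome 17 held 12.1% against 3.90% (odds ratio 3.40, 2.41 to 4.93), chromosome 16 held 10.2% against 4.87% (2.23, 1.63 to 3.12) and chromosome 22 held 6.67% against 2.49% (2.80, 1.82 to 4.50). These 4 were the chromosomes with a higher share in KO by Fisher's exact test at an adjusted p under 0.05, the adjusted p being 1.4e-24 for chromosome 19. Chromosomes 2, 3, 4, 5, 6, 8, 10, 13, 15, 18 and Y, 11 of the 24 tested, had a lower share. A lower share was not a lower number, since 9 of these 11 held more KO than WT peaks. Chromosome 18, a gene-poor chromosome, held 0.436% of KO pemetrexed peaks (23) and 2.60% of WT pemetrexed peaks (24, odds ratio 0.164, 0.0882 to 0.305). Chromosome 2 held 3.56% (188) against 10.7% (99, odds ratio 0.308, 0.237 to 0.401). With peaks within 100 kb joined, 6 chromosomes passed instead of 15, 2 of them with a higher share in KO.

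After cisplatin, chromosome shares were closer between the genotypes. Chromosome 19 held 7.46% of KO and 6.81% of WT cisplatin peaks (odds ratio 1.10, 0.888 to 1.38), and chromosome 17 held 6.59% and 7.91% (0.821, 0.665 to 1.02). Of the 24 chromosomes, 1 passed Fisher's exact test, chromosome Y, with 24 KO and 0 WT peaks (adjusted p 0.010). It did not pass with peaks within 100 kb joined or with peaks of at least 600 bp alone. Chromosomes 16, 17, 19 and 22 together held 24.3% of KO cisplatin peaks (95% exact binomial interval 23.1 to 25.6%), 22.5% of WT cisplatin peaks (20.6 to 24.5%), 14.5% of WT pemetrexed peaks (12.3 to 16.9%) and 43.3% of KO pemetrexed peaks (41.9 to 44.6%). They make up 9.37% of the span covered by the lists. The WT pemetrexed share was below both cisplatin shares, so the pemetrexed contrast does not rest on the KO list alone. The gene-poor chromosomes 4, 13 and 18, with 12.8% of the span, held 3.52% of KO pemetrexed peaks, 9.09% of WT pemetrexed peaks, 6.37% of KO cisplatin peaks and 6.20% of WT cisplatin peaks. The KO over WT odds ratio of the gene-dense group was 4.06 times as high for pemetrexed as for cisplatin (95% Wald interval 3.23 to 5.12). This group is the same 4 chromosomes called higher in KO after pemetrexed. Chromosomes 4, 13 and 18 were all among those called lower. The pemetrexed contrast was thus known when the groups were made, which the interval does not allow for.

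**Figure D2:**
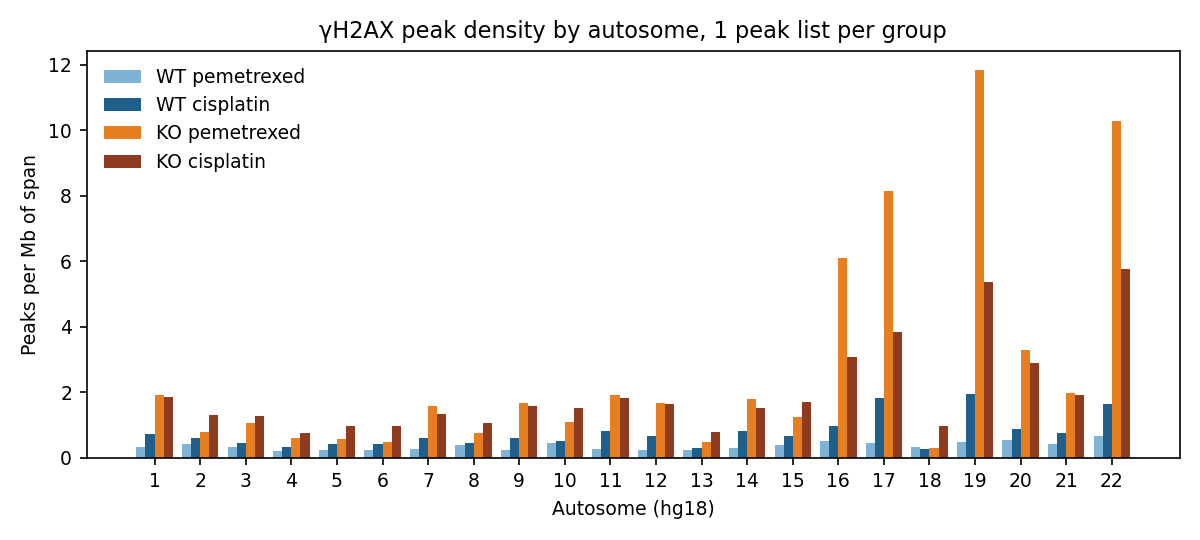
Peaks per Mb of chromosome span (y axis) for each autosome (x axis), with 1 bar for each of the 4 lists and no replicates. KO pemetrexed reached 11.8 peaks per Mb on chromosome 19, 10.3 on chromosome 22, 8.14 on chromosome 17 and 6.11 on chromosome 16, against 0.304 on chromosome 18.

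The KO pemetrexed peaks were gathered in a small part of the genome. Of 2847 windows of 1 Mb over all chromosomes, 82 (2.88%) held 50% of the KO pemetrexed peaks, while 273 windows were needed for WT pemetrexed, 253 for WT cisplatin and 290 for KO cisplatin. The window with the most peaks was on chromosome 19 (1000001 to 2000000), with 97 KO pemetrexed, 20 KO cisplatin, 9 WT cisplatin and 0 WT pemetrexed peaks. The first window of chromosome 16 (1 to 1000000) held 71, 16, 5 and 0 peaks in the same order. The other windows with the most KO pemetrexed peaks and no WT pemetrexed peak were 2 on chromosome 19 (4000001 to 5000000 with 59, and 10000001 to 11000000 with 55) and 1 on chromosome 16 (87000001 to 88000000 with 54, tied with 77000001 to 78000000 on chromosome 17). Also among the 5 windows with the most peaks over all lists were 88000001 to 89000000 on chromosome 16, with 65 KO pemetrexed peaks and 1 WT pemetrexed peak, and 77000001 to 78000000 on chromosome 17, with 54 and 0. Only 25.7% of the 2847 windows held any WT pemetrexed peak, so a count of 0 was the usual value for that list. It was also a condition of the rule that named some of these windows.

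**Figure D3:**
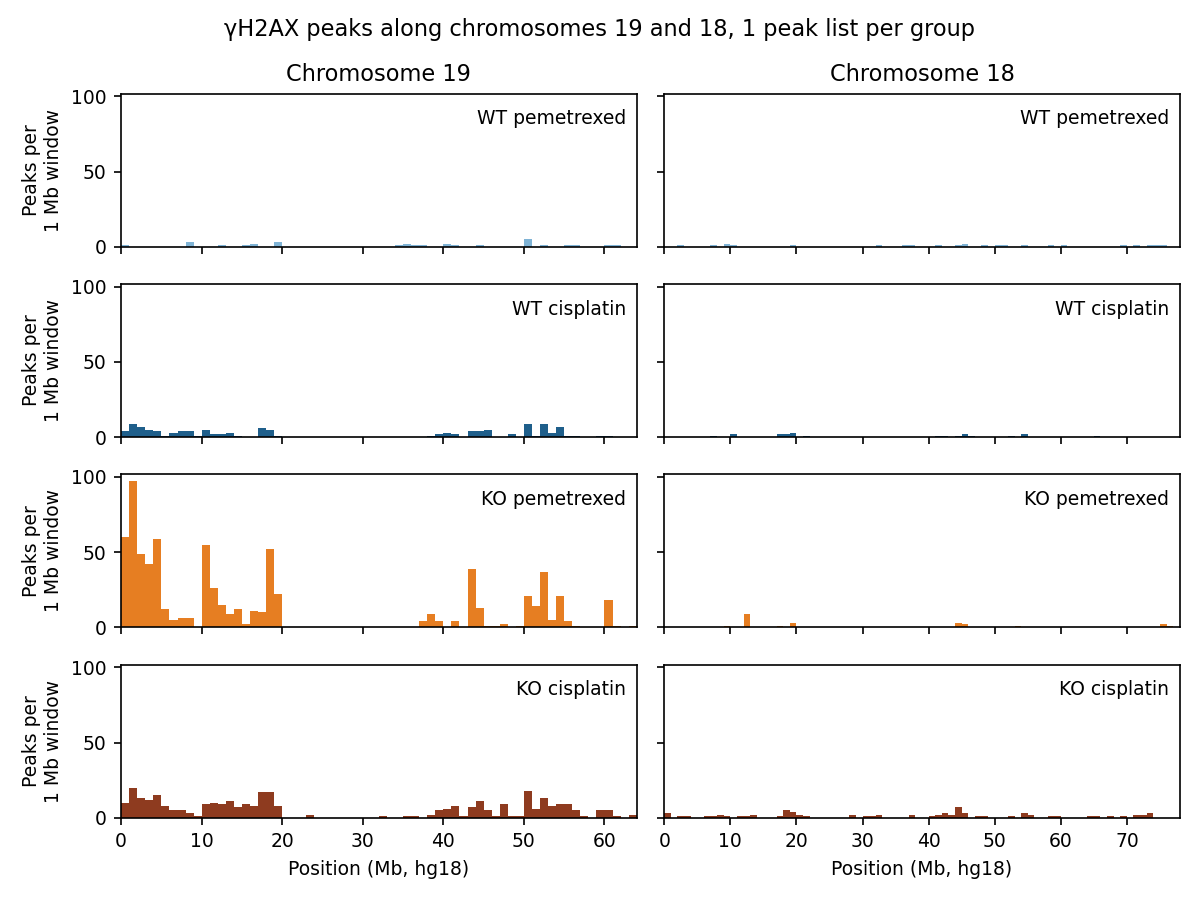
Number of peaks per 1 Mb window (y axis, same scale in every panel) along chromosome 19 (left) and chromosome 18 (right) in hg18 coordinates, with 1 row of panels for each of the 4 lists. On chromosome 19 the KO pemetrexed list reaches 97 peaks in a window and the KO cisplatin list 20, while chromosome 18 holds 23 KO pemetrexed peaks in all.

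Peaks lay closer together than random placement in all 4 lists. In the KO pemetrexed list, 88.4% of the 5272 placed peaks were within 100 kb of another peak, against 50.7% by random placement. The KO cisplatin list had 57.1% against 33.5%, WT cisplatin 30.0% against 15.1%, and WT pemetrexed 12.6% against 6.77%. Each difference had an adjusted permutation p of 1e-04, the smallest the placements can give. Because longer lists have closer peaks, the lists were also thinned to 916 peaks each. The median share was then 57.3% for KO pemetrexed (95% of draws 53.6 to 60.7%), 20.7% for KO cisplatin (17.7 to 24.1%), 17.7% for WT cisplatin (14.9 to 20.5%) and 12.6% for WT pemetrexed. At a distance of 1 Mb the KO cisplatin list no longer exceeded random placement (94.1% against 94.4%).

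Few peaks lay at the same place in different lists, although every pair shared more than circular shifts gave. Of 916 placed WT pemetrexed peaks, 13 met a KO pemetrexed peak (1.42%, 95% exact binomial interval 0.758 to 2.42%) against 4.87 by shifts, 2.67 times as many (adjusted permutation p 0.0028). This call was lost without chromosomes 16, 17, 19 and 22 (5 peaks, 2.36 times the shifts, adjusted permutation p 0.069) and with peaks of at least 600 bp alone (3 peaks, 1.60 times the shifts, adjusted permutation p 0.28). Of 1805 WT cisplatin peaks, 32 met a KO cisplatin peak (1.77%, 1.22 to 2.49%), 5.31 times the number by shifts and 2.72 times that by local shifts of 100 kb to 1 Mb, which keep the regional density of peaks. Between drugs in KO cells, 334 of 4562 cisplatin peaks met a pemetrexed peak (7.32%, 6.58 to 8.12%), 8.73 times the number by shifts and 3.52 times that by local shifts. Between drugs in WT cells, 10 of 916 pemetrexed peaks met a cisplatin peak (1.09%, 0.525 to 1.998%), 11.9 times the number by shifts. The pairs that differ in both drug and genotype also shared peaks. Of the WT cisplatin peaks, 72 met a KO pemetrexed peak (3.99%, 3.13 to 5.00%), 5.36 times the number by shifts and 2.08 times that by local shifts, and 11 WT pemetrexed peaks met a KO cisplatin peak (1.201%, 0.601 to 2.14%), 4.40 times the number by shifts. Each of these 5 pairs had an adjusted permutation p of 0.00012 against circular shifts. Which control library each list was called against is not given in the sources used here, and lists of the same genotype could share one, so part of the excess between drugs may come from it. No region had a peak in all 4 lists.

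Of the 12088 regions covered by any list, 11 had a peak in 3 lists. They were named after their values were seen. In 9 of them the peaks came from both KO lists and the WT cisplatin list. These included 8631 bp on chromosome 19 (18472272 to 18480903), 7407 bp on chromosome 9 (129672196 to 129679603), 3385 bp on chromosome 19 (11466773 to 11470158) and 2486 bp on chromosome 22 (44006560 to 44009046). The other two, both on chromosome 17, held a WT pemetrexed peak. One (1057981 to 1058844) also had WT cisplatin and KO pemetrexed peaks, and the other (70839250 to 70840159) had peaks of both KO lists.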

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

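The tests of a deeper library and of a fixed difference of the knockout line, the random placements before joining, the groups of chromosomes and the distance from the first and last covered positions were chosen after the results were seen. The KO over WT ratio of peak numbers differed between the drugs by a factor of 2.26 (95% interval 2.07 to 2.47), the KO drug ratio of 1.15 divided by the WT drug ratio of 0.511, and with peaks within 100 kb joined the factor turned to 0.754 (0.676 to 0.841) and the KO drug ratio to 0.43. A deeper library that found the same sites would place most WT pemetrexed peaks on KO pemetrexed peaks. Of them, 1.42% lay on one (95% interval 0.758 to 2.42%), below the 50% set for this explanation after the results were seen. Any pair of these lists would have failed that mark, so it decides nothing. Every pair of lists shared few peaks, from 1.09% for the drugs in WT to 7.32% for the drugs in KO. A low share therefore does not separate depth from other differences. A depth difference, whether or not it also changes which sites are called, stays open, since no depth is known. Wide domains split into several peaks may account for part of the excess in number and stay open, since joining peaks within 100 kb left a pemetrexed KO over WT ratio of 1.41 (1.29 to 1.54), between the bounds set for and against this explanation, while joining randomly placed peaks gave 3.94. With 1 library per group, a difference between single libraries cannot be told apart from loss of UNG.

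The KO over WT odds ratio of a peak lying on the gene-dense chromosomes 16, 17, 19 and 22 was 4.06 times as high for pemetrexed as for cisplatin (95% interval 3.23 to 5.12), and that for chromosomes 4, 13 and 18 was 0.355 times as high (0.250 to 0.504). Both groups lie within the chromosomes called from the same pemetrexed lists. These values and the pemetrexed odds ratio are therefore not independent of the choice of groups. A fixed difference of the knockout line, such as extra copies of these chromosomes, would raise their share in the KO cisplatin list as well, but the odds ratio there was 1.11 (0.970 to 1.26) against 4.49 (3.71 to 5.48) for pemetrexed, which argues against it as the whole cause. Few wide domains counted many times stay open, since joining peaks within 100 kb gave odds ratios of 2.04 (1.59 to 2.61) for pemetrexed and 0.841 (0.714 to 0.991) for cisplatin, but joining randomly placed peaks also gave 2.13 for pemetrexed, so the fall decides nothing. Base composition of the library could not be tested, because 0 peaks were given a sequence here, and gene-dense chromosomes are also rich in G and C. An effect of pemetrexed in cells without UNG stays open and untested beside it.

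The KO over WT odds ratio of a peak lying within 5 Mb of the first or last position covered on its chromosome (the last alone on chromosomes 13, 14, 15, 21 and 22) was 4.17 times as high for pemetrexed as for cisplatin (95% interval 3.23 to 5.38). Outside the compared chromosomes, unplaced contigs held 8 of 924 WT pemetrexed, 6 of 5278 KO pemetrexed, 8 of 4570 KO cisplatin and 2 of 1807 WT cisplatin peaks. The share was highest in the WT pemetrexed list. All but the WT cisplatin count exceeded 3, the value used to flag them, which tests no difference between lists.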

How the results depend on the processing

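Alternatives on peak width, on joining within 100 kb for the ratios, on leaving out chromosomes 16, 17, 19 and 22 and on local shifts were chosen after the data were seen. Of 97 alternative values for 19 results, 62 kept their direction and their side of the threshold, stayed within the interval or, for numbers of chromosomes, within 1.5 times, 28 moved, 2 lost their call and 5 reversed. No paired analysis was possible because each group has 1 library. Values are given in the order KO over WT peaks for pemetrexed, the same for cisplatin, pemetrexed over cisplatin in WT and in KO, the ratio of ratios, and covered bases KO over WT for pemetrexed and for cisplatin. Joining within 10 kb moved the KO over WT peak ratios to 3.76 and 2.355, the KO drug ratio to 0.815 (reversed), the ratio of ratios to 1.60 and the bases to 24.35 and 3.99. After joining, at either distance, the bases include the gaps between joined peaks and are not bases covered by peaks alone. Joining within 100 kb gave 1.41, 1.87, 0.572, 0.43 (reversed), 0.754 (reversed), 34.0 and 4.49. Joining randomly placed peaks within 100 kb gave 3.94, 2.22, 0.532, 0.945 and 1.78 for the ratios of peak numbers, so that a part of these shifts comes from joining itself. Peaks of at least 600 bp gave 15.6, 3.83, 0.313, 1.27, 4.06, 37.4 and 4.61, a filter that favours the lists with wider peaks. Without chromosome 19, the pemetrexed ratio was 5.06, the KO drug ratio 1.07, the ratio of ratios 2.02 and the pemetrexed bases 14.3. Without chromosomes 16, 17, 19 and 22 these were 3.79, 0.866 (reversed), 1.535 and 10.2, and the WT drug ratio was 0.564. The WT and KO pemetrexed overlap lost its call with peaks of at least 600 bp (1.60 times the shifts) and without those 4 chromosomes (2.36 times). Every other overlap kept its call, but local shifts lowered the folds over chance from 8.73 to 3.52 for the drugs in KO, from 5.31 to 2.72 for WT and KO cisplatin, from 5.36 to 2.08 for WT cisplatin and KO pemetrexed, from 11.9 to 9.255 for the drugs in WT, from 4.40 to 3.56 for WT pemetrexed and KO cisplatin, and from 2.67 to 2.13 for WT and KO pemetrexed. Chromosomes with a different share fell from 15 to 6 for pemetrexed with joining within 100 kb and to 10 with peaks of at least 600 bp, and for cisplatin from 1 to 0 both with joining and with peaks of at least 600 bp. The clustering of KO cisplatin peaks counted as reversed at 1 Mb (94.1% of peaks), where random placement gave 94.4%. Random placement alone left little room for an excess there, so this is an absent excess and not an opposite effect. The cause of these changes was not tested. Unknown depth limits every comparison of list lengths, and score and false discovery rate alternatives could not be run.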

Other observations

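The comparisons of the first and last covered positions and of window counts were chosen after the data were seen. KO pemetrexed peaks were frequent near the first and last covered positions of the autosomes. The starts of chromosomes 13, 14, 15, 21 and 22, where coverage begins far from the end, were not counted, while that of chromosome 6, where it begins at 5630493, was. Of the peaks on autosomes, 36.9% (95% exact binomial interval 35.6 to 38.3%) lay within 5 Mb of the first or last position covered on their chromosome, stretches that hold 7.05% of the span. The share was 18.6% for KO cisplatin, 17.4% for WT cisplatin and 11.4% for WT pemetrexed. Without chromosomes 16, 17, 19 and 22 it was still 31.7% for KO pemetrexed, against 10.6% for WT pemetrexed. The KO share was higher than the WT share on 17 of 22 autosomes after pemetrexed and on 15 of 22 after cisplatin.

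Counts of peaks per 1 Mb window were correlated between lists across 2785 autosomal windows, which are not independent replicates. Counts per window of KO pemetrexed and KO cisplatin had a Spearman rho of 0.571 (Pearson r 0.688), those of WT cisplatin and KO pemetrexed 0.516 (r 0.594), and those of WT cisplatin and KO cisplatin 0.473 (r 0.624). The WT pemetrexed list had a rho of 0.139 with WT cisplatin (r 0.158), 0.172 with KO pemetrexed (r 0.116) and 0.220 with KO cisplatin (r 0.203). Shifts of the windows along the chromosomes gave a mean rho of 0.0228 to 0.0985 and an adjusted permutation p of 0.0005 in all 6 pairs, the smallest that 2000 shifts can give. Whether these correlations differ from each other was not tested.

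Chromosome X held 0 WT pemetrexed, 2 WT cisplatin, 2 KO pemetrexed and 6 KO cisplatin peaks, all between positions 48332904 and 61800030. The largest of these shares was 0.131% (KO cisplatin), and in every list each autosome held more peaks than X. Any filter used before the lists were made is not given, and the cause was not tested. The genotype comparison on X therefore says little. Chromosome Y held 24 KO cisplatin and 5 WT pemetrexed peaks. The KO cisplatin peaks there lay either between 10626171 and 12373756 or between 27193420 and 27211796, with none between these stretches.

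Several of the widest WT pemetrexed and KO cisplatin peaks led to the hypothesis that these 2 lists may be rich in peaks beside long stretches without peaks. On 17 autosomes, the share within 2 Mb of the longest stretch without a peak in the other lists was 0.910 times that of the span for WT pemetrexed (95% interval 0.566 to 1.38), 1.09 times for KO cisplatin (0.911 to 1.29), 0.684 times for WT cisplatin (0.469 to 0.962) and 0.272 times for KO pemetrexed (0.192 to 0.374). These places covered 0 of the 5 widest WT pemetrexed peaks and 1 of the 5 widest KO cisplatin peaks. Peaks inside the stretches were left out of these shares. On chromosome 16 the stretch (33810139 to 44963900) held the widest WT pemetrexed peaks there (44945424 to 44946942 and 44958306 to 44959528). An upper bound below 1.5 times the share of the span had been set before the test as counting against the hypothesis. Both lists met this (1.38 for WT pemetrexed and 1.29 for KO cisplatin), so the counted peaks showed no excess of that size. The test still missed most of the peaks that prompted it, some of them by its construction, and for these it leaves the hypothesis open.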
